A study of Solanum lycopersicum with 12 samples.

How the data were processed

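RNA was sequenced from the apical meristem of 4-week tomato plants (Solanum lycopersicum, cultivar Rutgers), the growing shoot tip that holds the stem cells and the youngest leaf primordia. The 12 libraries fall into 4 groups of 3, which the labels call biological replicates. The groups are wild type, 2 lines labelled as mutants of MSH1 (Dwarf-dr and mild-dr), and a line labelled epiF3. MSH1 encodes a plant homolog of the bacterial mismatch repair protein MutS that is targeted to mitochondria and plastids. Per the labels' protocols, plants grew in a greenhouse with 15 h days and 9 h nights, RNA was extracted with TRIzol and cleaned on columns, and TruSeq libraries were sequenced as single reads of 100 bp. The edgeR p-values of single genes measure the spread between these samples. The Fisher's exact and permutation p-values take genes or loci as units, which are not replicates, and do not measure that spread.

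The authors deposited 3 tables of raw read counts per locus, each holding a line beside the same 3 wild type libraries, and 3 tables of their own calls. The deposited counts are whole numbers and were not normalized, per the file headers and the values. The submitters' processing notes name FastQC, Bowtie2, TopHat2 2.0.10, DESeq2 and Cuffdiff, without role or order. The genome build, the annotation release, the read counter and its use of strand are not given in the sources used here. In the tables of calls, the authors give a log2 fold change, an adjusted p-value and the percent identity of each locus to its closest Arabidopsis homolog. A linear fold change is also deposited for epiF3, per the file headers. These tables hold 3165 loci for Dwarf-dr, 341 for mild-dr and 473 for epiF3, all with an adjusted p-value under 0.05 in the authors' test.

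The count tables held 26223 loci for Dwarf-dr, 26076 for mild-dr and 26182 for epiF3, and were joined by locus into 26985. The wild type counts in the 3 tables never disagreed. A locus left out of a table was taken as 0 there, since each table lists only loci with at least 1 count. Totals per library ran from 14313264 to 25582357, and 3 counts, the floor used for a count of 0, came to between 0.115 and 0.223 CPM. Intervals and floors cover counting error only. Product names come from the authors' tables of calls and so exist for 3528 loci (13.1%). The reference table of gene names matched 0 of the locus identifiers and was not used. The chromosome of a locus is the number in its identifier, and coordinates are not analysed here. Members of tandem families, such as the glutathione S-transferases, phenylalanine ammonia-lyases, osmotins, heat shock proteins, NBS-LRR genes and major latex-like proteins, are uncertain where reads of near-identical copies could have been divided between them, and so are overlapping loci.

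Each of the 6 pairs of groups was tested on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling and the quasi-likelihood F test, with no covariate. The Benjamini-Hochberg adjustment at 0.05 was applied with no minimum fold. Every adjusted p-value of a gene in the text is from this test unless another is named. Levels are TMM-scaled CPM as edgeR computes them, given as mean ± SD over 3 libraries, and the error of a log2 fold change is its standard error. Where a group had 0 counts the fold is a bound against 3 counts per library. With 1 to 3 counts it is a ratio of counts with a 95% interval. These choices, the gene lists and the rule for naming genes were written before the data were examined, but the list test that the rule refers to was chosen afterwards, as given below. The rule took the MSH1 gene, the 6 largest rises and the 6 largest falls per comparison among called genes with a named product, a mean log2 level of at least 1 and no overlap between the groups. It also took the 2 members with the smallest p-value from each list past its test and from the 6 lists with most called members. Not every gene so selected is named, and the choice among them was made after their values were seen. Genes named as exceptions inside a list (a cyclin B1, a ribosome-recycling factor, an expansin-like and a cytochrome c oxidase gene) were chosen after their values were seen.

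The 32 gene lists are patterns on the product names. They cover hormones, stress and defence, organelles, cell division, cell wall, epidermis, meristem and floral regulators, chromatin and repeats, metabolism, and markers of other tissues that a dissected apex could hold. Because product names came only with loci the authors had called in at least 1 line, membership was itself selected on these samples. A list's count, also with p-values adjusted over that list alone, is therefore not independent evidence of its direction. The plan for that case was to give counts without a test. A Fisher's exact test of the direction of a list's called members against all other called, described genes was added after the data were seen, for lists with at least 5 called members, with Benjamini-Hochberg adjustment over the lists. Tests with limma 3.58.1 (camera with a preset correlation of 0.01, camera with an estimated correlation, and fry) were run beside it over the described genes.

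On simulated counts with 200 changed genes, the test recovered 55 of 100 genes changed 2-fold and 93 of 100 changed 4-fold for Dwarf-dr against wild type, over 20261 genes tested. For mild-dr against wild type it recovered 80 and 97 of 100 over 20139 genes, and for epiF3 76 and 96 of 100 over 20222. False calls made up 8.08%, 8.29% and 7.53% of the calls in these simulations, above the nominal level. The direction test passed 0.05 for 2.8% of 500 random lists drawn for Dwarf-dr. Members of these lists were drawn independently from the called genes. The check therefore does not cover lists of correlated members, such as cell cycle (correlation of 0.468 as estimated by camera).

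The labels give the replicates of every group the numbers 1 to 3. For Dwarf-dr and wild type, deviations from the group means correlated between libraries of the same number by 0.315, 0.174 and 0.26, and all 6 libraries correlated best with their own number. Those 2 groups therefore looked paired by number, from the data and not from any label. The main test still used no covariate and so ignores this pairing. For those 2 groups, a fit with the replicate number as a block is given where it changed the call of a list or of a gene the naming rule selected. Alternatives tried were another scaling, DESeq2 1.42.0, no filter, a stricter filter, a minimum fold of 1.5, all 12 libraries in a single fit, the replicate block and leaving out each library. A fit without both libraries numbered 1 of Dwarf-dr and wild type was added after seeing the data. The 3 comparisons against wild type share their controls, so their overlap was set beside 20 simulations of unchanged groups. No pair of replicates agreed within sampling noise, so none was counted as a single library. By chi-square per degree of freedom, Dwarf-dr replicates 2 and 3 came closest, at 3.235. A spread above sampling noise cannot by itself show that libraries came from separate plants.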

Results

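The transcriptomes of 4-week apical meristems were compared between wild type tomato, the lines labelled Dwarf-dr and mild-dr, which are given as MSH1 mutants, and the line labelled epiF3. Each group had 3 libraries. The total count was 22429402, 24517895 and 19489874 in wild type replicates 1 to 3, 14313264, 24109598 and 20076991 in Dwarf-dr, 23682615, 22165241 and 19005380 in mild-dr, and 24131545, 25582357 and 25136226 in epiF3. Between 23559 and 24516 loci had a count in a library, and the 10 most abundant loci took 9.8 to 12.3% of the counts. The lines are called by their labels throughout, since nothing measured here shows which genotype a library carries.

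The locus described as MSH1, Solyc09g090890.1, is annotated as a MutS-type mismatch repair protein with 65.31% identity to its Arabidopsis homolog AT3G24320 in the authors' deposited table. It was close to the limit of detection, with 4, 4 and 3 counts in the wild type libraries, 11, 9 and 13 in Dwarf-dr, 8, 6 and 6 in mild-dr and 3, 7 and 4 in epiF3. Its level was 0.17 ± 0.00555 CPM in wild type and 0.597 ± 0.23 in Dwarf-dr (SD, n = 3), higher in 3 of 3 libraries, a log2 difference of 1.72 ± 0.51 that did not pass (edgeR without the filter on low counts, adjusted p = 0.0805). The authors' deposited table lists it as higher in Dwarf-dr, with a log2 fold change of 1.09 and an adjusted p-value of 0.0468. In mild-dr it stood at 0.302 ± 0.0307 (edgeR adjusted p = 0.68) and in epiF3 at 0.185 ± 0.0734 (edgeR adjusted p = 0.988). At 3 to 13 counts this locus cannot check the labels. Its description covers only the C-terminal MutS domain, and whether it holds the whole gene is not given in the sources used here. A nearby locus without a description, Solyc09g090870.2, looked up after the results were seen, was not called either in Dwarf-dr, mild-dr or epiF3 (log2 fold change 0.23 ± 0.32, 0.01 ± 0.12 and 0.20 ± 0.10, edgeR adjusted p = 0.721, 0.986 and 0.683), and it is not known here whether it belongs to MSH1.

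The first comparison asked how the Dwarf-dr meristem differed from wild type. Alternative oxidase (Solyc08g075540.2), the mitochondrial enzyme that passes electrons to oxygen around the cytochrome pathway, stood at 97.4 ± 10.6 CPM in Dwarf-dr against 2.83 ± 0.518 in wild type (SD, n = 3). An NADH dehydrogenase-like gene (Solyc02g079170.2) stood at 133 ± 4.46 against 9.3 ± 2.21, and heat shock protein 22 (Solyc08g078700.2) at 204 ± 39.6 against 3.06 ± 0.539. A 3-ketoacyl-CoA synthase gene (Solyc05g009270.2), for an enzyme of the elongation of wax fatty acids, was lower, at 4.56 ± 0.552 against 35.5 ± 9.34. By edgeR at an adjusted p of 0.05, 1185 loci rose and 519 fell of 20419 tested, 930 of them by at least 2-fold.

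**Figure D1:**
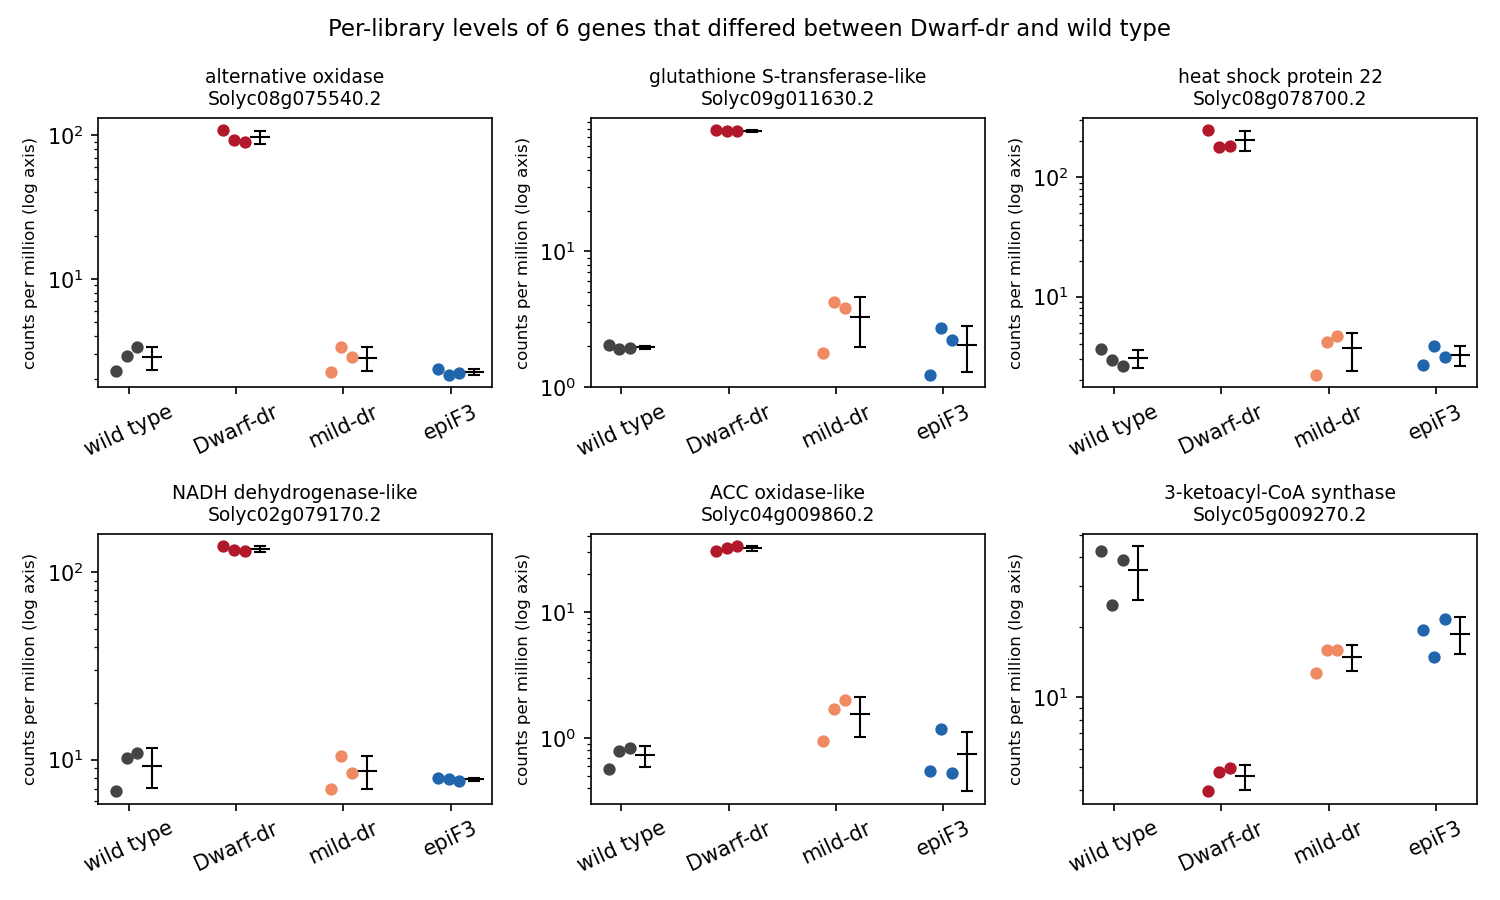
Level of 6 genes in each of the 12 libraries, in CPM on a log axis, by group; points are libraries and bars the mean ± SD (n = 3). Alternative oxidase stands at 97.4 ± 10.6 in Dwarf-dr and 2.83 ± 0.518 in wild type, and the 3-ketoacyl-CoA synthase at 4.56 ± 0.552 and 35.5 ± 9.34.

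The largest rises in Dwarf-dr included genes with few or no reads in wild type. A pentatricopeptide repeat gene (Solyc06g009490.2), of a family that processes organelle RNA, was at least 48.1-fold higher than the 0 counts of wild type, and an ARID-domain DNA-binding protein gene (Solyc10g012210.1) at least 36.5-fold. A lysyl-tRNA synthetase gene (Solyc10g076610.1) had a count ratio of 1110 (95% interval 306 to 9130) and an exonuclease gene (Solyc01g068040.1) of 185 (50.9 to 1540). The fitted log2 fold change of the latter was 7.29, but 6.69 without wild type replicate 2, and 9.94 without wild type replicate 3, which held its only wild type counts. A cytochrome P450 (Solyc07g041500.2) rose by 8.59 ± 0.29 on the log2 scale (edgeR adjusted p = 6.23e-06). GH3.8 (Solyc01g107400.2), of a family that conjugates auxin to amino acids, rose by 7.43 ± 0.42 (edgeR adjusted p = 7.66e-05), and by 8.64 without wild type replicate 3. Among the largest falls, a homeobox gene described as PROTODERMAL FACTOR 2 (Solyc06g035940.2), a regulator of epidermal identity, dropped from 205 ± 33 to 0.146 ± 0.12 CPM (log2 fold change −10.34 ± 0.33, edgeR adjusted p = 5.98e-06, and −11.3 without Dwarf-dr replicate 3). A glutaredoxin gene (Solyc06g008760.1) was lower by a count ratio of 404 (95% interval 72.2 to 16000), with a fitted log2 of −8.18, but −7.54 without Dwarf-dr replicate 2, and −10.2 without Dwarf-dr replicate 1, which held its only Dwarf-dr count. A phosphatase 7 homolog (Solyc10g085700.1) fell by 6.38 ± 0.31 and a serine/threonine kinase (Solyc08g082980.2) by 6.11 ± 0.30 (−6.95 without Dwarf-dr replicate 2). A 3-phosphoshikimate 1-carboxyvinyltransferase gene (Solyc09g005460.1), of aromatic amino acid synthesis, fell by 3.84 ± 0.36. Its counts varied within the other lines, at 11, 13 and 86 in mild-dr replicates 1 to 3 and 13, 100 and 19 in epiF3. Every gene named here differed the same way in 3 of 3 Dwarf-dr libraries, which the naming rule required of the largest changes.

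Among the gene lists, 3 passed the direction test, each with more falls than rises. In the cell cycle list 20 of 51 tested members fell and 2 rose (Fisher's exact test of direction, adjusted p = 1.45e-07). By limma's camera this list stood apart from other genes at the preset correlation (adjusted p = 1.23e-06) but not with an estimated correlation (adjusted p = 0.602). The fallers were kinesins, which move spindle microtubules, cyclins of the A, B and D types and replication licensing factors. Kinesins Solyc07g064030.2 and Solyc07g065210.2 fell by 0.73 ± 0.13 and 0.93 ± 0.17 on the log2 scale (edgeR adjusted p = 0.0161 and 0.0179, 3 of 3 libraries). Without Dwarf-dr replicate 2 both had an edgeR adjusted p of 0.0653, and the latter had 0.058 without Dwarf-dr replicate 3 and 0.0592 without wild type replicate 2. The risers were a cyclin B1 gene (Solyc06g073610.2, by 1.05 ± 0.22) and a ribosome-recycling factor gene (Solyc11g007740.1), which acts in translation and is in the list only through its name. Of the members, 48 passed when p-values were adjusted over the list alone. In other lists this count ran from 2 of 8 trichome markers to 24 of 24 abscisic acid and dehydration members. Members are loci the authors had already called, so such counts do not set a list apart. Wild type replicate 1 stood 0.393 log2 units above replicates 2 and 3 in this list and Dwarf-dr replicate 1 0.134 units below its own (-0.134). Without wild type replicate 1, 7 members fell and 2 rose (Fisher's exact test, adjusted p = 0.0113). With wild type replicate 2, Dwarf-dr replicate 2 or Dwarf-dr replicate 3 left out, 1, 0 and 1 members fell and 0 rose by edgeR, too few for the direction test. Without both libraries numbered 1, 42 fell and 5 rose.

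In the list of cell wall expansion, 10 of 30 members fell and 3 rose (Fisher's exact test, adjusted p = 0.00651), a call limma's camera gave at the preset correlation (adjusted p = 0.0165) but not with an estimated correlation (adjusted p = 0.223). Xyloglucan endotransglucosylase Solyc02g080160.2, which cuts and rejoins wall xyloglucan, fell by 0.85 ± 0.13 (edgeR adjusted p = 0.00886). Pectate lyase Solyc03g058910.2 fell by 2.28 ± 0.36 (edgeR adjusted p = 0.00907), while an expansin-like gene (Solyc08g077330.2) rose by 2.78 ± 0.20. The direction of this list was no longer called without wild type replicate 2 (Fisher's exact test, adjusted p = 0.204), without wild type replicate 3 (adjusted p = 0.0789) or with the stricter filter (adjusted p = 0.178), and without Dwarf-dr replicate 2 or 3 it had 3 and 4 called members, too few to test. In the lipid transfer and cuticle list 13 of 48 members fell and 6 rose (Fisher's exact test, adjusted p = 0.00651). Limma's camera gave this call too at the preset correlation (adjusted p = 0.0152) but not with an estimated correlation (adjusted p = 0.359). Besides the 3-ketoacyl-CoA synthase (log2 fold change −2.94 ± 0.23, edgeR adjusted p = 0.000363), most fallers were GDSL esterases, a family of lipid hydrolases, such as Solyc01g095450.2 (−1.68 ± 0.14, edgeR adjusted p = 0.00052). Adjusted over the list alone, 28 cell wall and 42 cuticle members passed.

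The lists of oxidative stress, ethylene, NAC, WRKY, mitochondrial, heat shock and pathogenesis-related genes each had more rises than falls. In the main fit, with all libraries and no covariate, none of them passed the direction test. In the oxidative stress list 32 of 73 members rose and 5 fell (Fisher's exact test, adjusted p = 0.0714, and 0.0235 without Dwarf-dr replicate 1), led by a glutathione S-transferase-like gene (Solyc09g011630.2) at 78 ± 1.12 against 1.96 ± 0.0566 CPM (edgeR adjusted p = 1.55e-06). The ethylene list had 20 rises and 2 falls of 43 (adjusted p = 0.0966 by Fisher's exact test, and 0.044 without Dwarf-dr replicate 1). Its members include an ACC oxidase (Solyc07g049530.2), which makes ethylene, up by 2.61 ± 0.14 (edgeR adjusted p = 5.92e-05), and an ACC oxidase-like gene (Solyc04g009860.2), up by 5.47 ± 0.16 (edgeR adjusted p = 5.38e-06). NAC transcription factors had 11 rises and 0 falls of 16 tested by edgeR (Fisher's exact test, adjusted p = 0.0714, 0.0326 with the replicate block and 0.0113 without Dwarf-dr replicate 1), and WRKY factors 8 rises and 0 falls of 16 (adjusted p = 0.163 by Fisher's exact test, and 0.0339 without Dwarf-dr replicate 1). The mitochondrial list had 21 rises and 4 falls of 48 (adjusted p = 0.244 by Fisher's exact test), among them the import subunit TIM14 (Solyc06g072330.2) at 82.4 ± 14.6 against 1.54 ± 0.419 CPM. Several of its risers are loci on nuclear chromosomes whose listed homologs are genes of the Arabidopsis mitochondrial genome, such as a cytochrome c oxidase subunit 2 locus (Solyc11g056410.1, up by 2.56 ± 0.35). Heat shock and chaperone genes had 16 rises and 12 falls of 59, and pathogenesis-related genes 24 and 12 of 75, of which several risers are ethylene response factors matched through their domain text. Examples are an osmotin-like gene (Solyc08g080650.1, up by 3.92 ± 0.21, edgeR adjusted p = 5.8e-05) and an endochitinase (Solyc10g055810.1, up by 2.14 ± 0.13, edgeR adjusted p = 0.000126), both defence proteins.

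Of the other hormone lists, auxin had 14 rises and 9 falls of 41, with an auxin-repressed gene (Solyc03g006360.2) up by 4.57 ± 0.66 (edgeR adjusted p = 0.00661), and by 6.49 without wild type replicate 1. Gibberellin had 8 and 2 of 19, abscisic acid and dehydration 10 and 2 of 24, jasmonate and wounding 3 and 0 of 11, cytokinin 1 and 1 of 4, and brassinosteroid 2 and 0 of 2. Meristem regulators had 4 rises and 8 falls of 20 (Fisher's exact test, adjusted p = 0.0537). Their direction passed without wild type replicate 1, 2 or 3 (adjusted p = 0.0113, 0.043 and 0.0122 by Fisher's exact test) and without Dwarf-dr replicate 2 or 3 (0.0234 and 0.00631), but not without Dwarf-dr replicate 1 (0.213), with the replicate block (0.416) or by limma's camera (adjusted p = 0.299 at the preset and 0.602 with an estimated correlation). Apart from the homeobox gene above, the fallers included YABBY factors, which shape leaf and floral organs. The list of flowering genes had 7 rises and 11 falls of 26 (adjusted p = 0.0518 by Fisher's exact test, 0.0143 with the replicate block, where 6 rose and 13 fell, and 0.044 without Dwarf-dr replicate 1). Pentatricopeptide repeat genes had 13 rises and 3 falls of 37, phenylpropanoid genes 9 and 4 of 35, starch and sugar genes 5 and 1 of 12, ribosomal proteins 2 and 2 of 20 (3 and 9 without Dwarf-dr replicate 1, Fisher's exact test, adjusted p = 0.0463), silencing genes 2 and 0 of 12, transposons 1 and 3 of 8, and histones 0 and 1 of 3. Photosynthesis had 7 rises and 0 falls of 19, but 4 of the 7 are blue copper proteins, which are not part of the photosynthetic chain. Proteinase inhibitors had 5 and 1 of 8, and Dwarf-dr replicate 1 stood 1.62 log2 units above replicates 2 and 3 in that list. Of the markers of other tissues, vascular genes had 3 rises and 5 falls of 11, pollen and anther genes 4 and 1 of 10, and root genes 6 and 1 of 14. Trichome markers had 0 of 8 called by edgeR, and the clock list 0 of 1.

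**Figure D2:**
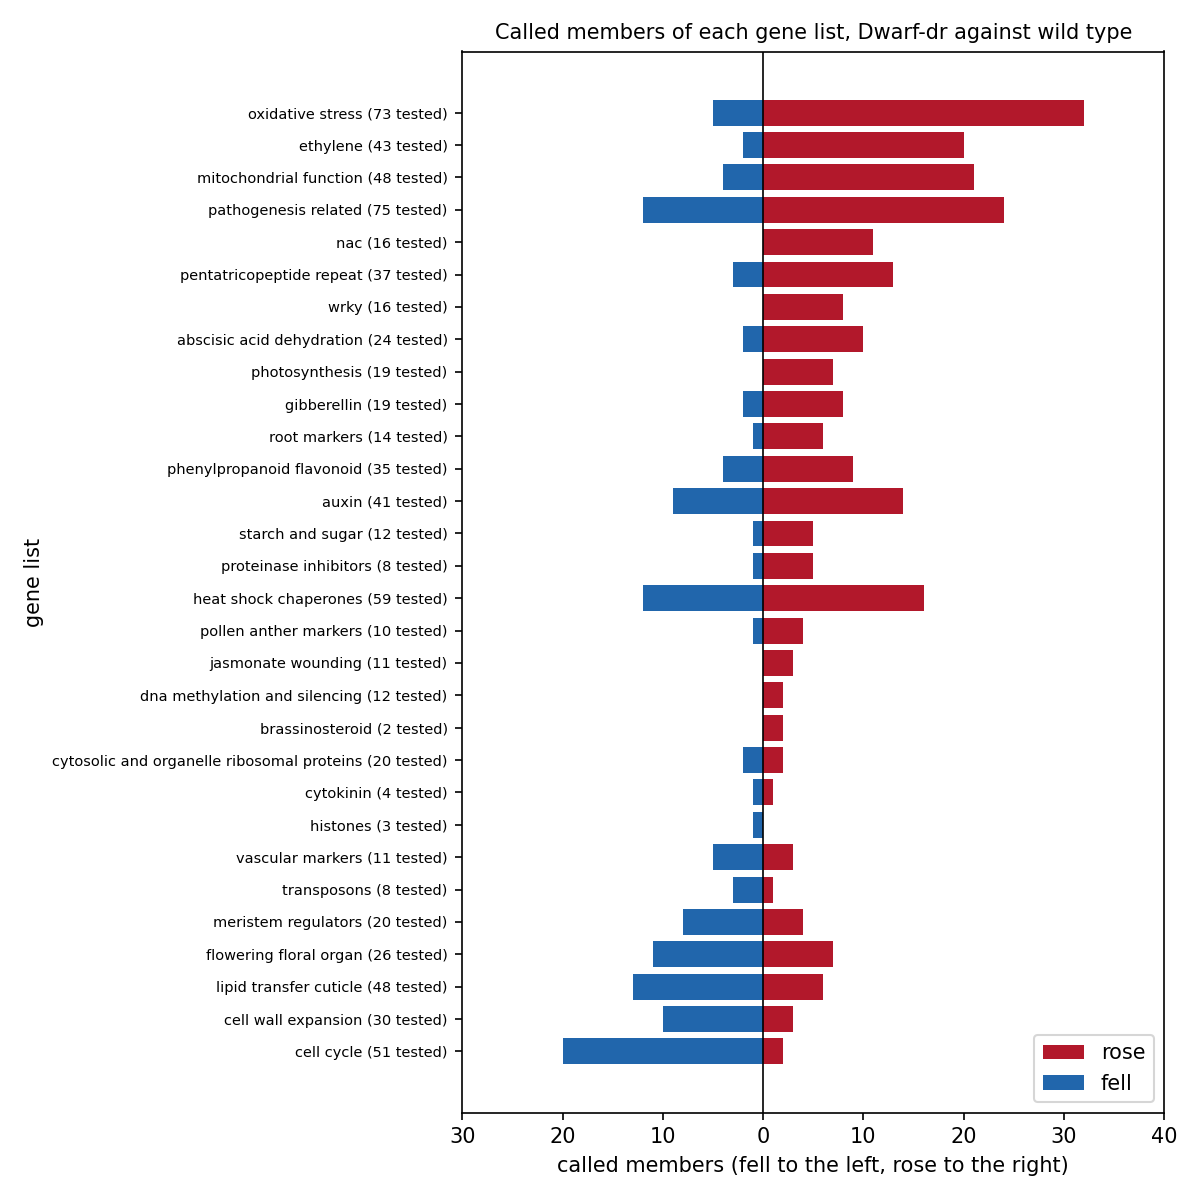
Number of members of each gene list that rose (bars to the right of 0) or fell (to the left) in Dwarf-dr against wild type, with the number tested beside each name. Cell cycle has 20 falls and 2 rises of 51, and oxidative stress 32 rises and 5 falls of 73.

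With libraries left out, the 1704 calls in Dwarf-dr became 1108, 665 and 870 without wild type replicate 1, 2 or 3, and 3125, 681 and 739 without Dwarf-dr replicate 1, 2 or 3. With the replicate block the rises were 1458 and the falls 788, and without both libraries numbered 1 there were 5416 calls.

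The second comparison asked the same of the mild-dr line. A gene for a resistance protein of the NBS-LRR class (Solyc09g092290.1), a family of intracellular immune receptors, stood at 3.77 ± 0.277 CPM against 0.0609 ± 0.0203 in wild type (SD, n = 3). Adenosine kinase (Solyc09g007940.2), which recycles adenosine, stood at 88.5 ± 35.9 against 3.11 ± 0.0982. The serine/threonine kinase Solyc08g082980.2 was lower, at 8.45 ± 0.766 against 18.9 ± 1.63. By edgeR, 55 loci rose and 19 fell of 20290 tested, 54 of the 74 by at least 2-fold.

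The NBS-LRR gene rose by 5.81 ± 0.31 on the log2 scale in mild-dr (edgeR adjusted p = 0.000219), adenosine kinase by 4.83 ± 0.32 (edgeR adjusted p = 0.000406), ubiquitin-conjugating enzyme 22 (Solyc06g051140.2) by 4.49 ± 0.31 and 3-hydroxyisobutyryl-CoA hydrolase (Solyc01g108800.2), of valine breakdown, by 3.86 ± 0.32. An ACC oxidase (Solyc10g018190.1), the only called ethylene gene, rose by 4.02 ± 0.46 (edgeR adjusted p = 0.00894), and by 4.69 without wild type replicate 2. The ARID-domain gene (Solyc10g012210.1) was at least 33.1-fold and the pentatricopeptide repeat gene Solyc06g009490.2 at least 25.1-fold higher than 0 counts in wild type. A dimerisation-domain gene of the HAT family (Solyc04g057790.1) rose by 4.84 ± 0.49 (edgeR adjusted p = 0.00445, and 0.0537 without wild type replicate 2), and by 5.88 without wild type replicate 1. The kinase fell by 1.16 ± 0.11 (edgeR adjusted p = 0.00357), and the phosphatase 7 homolog (Solyc10g085700.1) was lower by a count ratio of 203 (95% interval 55.9 to 1680). A cytidyltransferase gene (Solyc05g008870.2) fell by 0.93 ± 0.09. Each gene named for mild-dr differed the same way in 3 of 3 libraries, as the naming rule required of the largest changes.

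Of the 32 lists, 24 had 0 called members in mild-dr by edgeR, where 2055 of all loci had an unadjusted p under 0.05. None had the 5 needed for a direction test. At the preset correlation limma's camera called photosynthesis (lower, adjusted p = 0.0212). It also called pathogenesis-related, pentatricopeptide repeat, trichome, and pollen and anther genes (higher, adjusted p = 0.0257 each). With an estimated correlation none of these was called (camera adjusted p = 0.64 each). Photosynthesis had 2 falls of 14, both in loci whose homologs are plastid genes, CP47 of photosystem II (Solyc01g007500.2, −1.09 ± 0.16, edgeR adjusted p = 0.0302) and the large subunit of Rubisco (Solyc01g007330.2, −0.87 ± 0.13, edgeR adjusted p = 0.0364). Trichome markers had 2 rises of 9, a germacrene-D synthase (Solyc12g006570.1, 2.45 ± 0.39, edgeR adjusted p = 0.0438) and a sesquiterpene synthase (Solyc06g059930.2, 0.94 ± 0.15, edgeR adjusted p = 0.047). The pathogenesis-related list had 2 of 68, an endochitinase (Solyc10g055810.1, 0.88 ± 0.13) and a major latex-like protein (Solyc04g007680.2, 2.23 ± 0.35), and pentatricopeptide repeats 2 of 38. The 3-ketoacyl-CoA synthase fell by 1.25 ± 0.19 (edgeR adjusted p = 0.0408). Adjusted over the list alone, 8 trichome, 6 photosynthesis, 22 pathogenesis-related and 6 pentatricopeptide repeat members passed. Most of these calls were lost with a library left out. Without wild type replicate 2 the edgeR adjusted p became 0.111 for CP47, 0.174 for Rubisco, 0.288 for the germacrene synthase, 0.274 for the sesquiterpene synthase, 0.118 for the endochitinase and 0.281 for the latex-like protein, and in the same order without mild-dr replicate 1 it became 0.127, 0.123, 0.132, 0.111, 0.123 and 0.157, and without mild-dr replicate 3 0.133, 0.165, 0.106, 0.153, 0.128 and 0.154. Without mild-dr replicate 2 it became 0.0794 for CP47, 0.137 for Rubisco, 0.112 for the sesquiterpene synthase, 0.0654 for the endochitinase and 0.066 for the latex-like protein, and without wild type replicate 3 0.0542 for the germacrene synthase, 0.119 for the sesquiterpene synthase and 0.0652 for the endochitinase. For the 3-ketoacyl-CoA synthase it became 0.0928 without wild type replicate 3, and 0.157, 0.116 and 0.133 without mild-dr replicate 1, 2 or 3.

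The 74 calls in mild-dr became 1327 without wild type replicate 1, 28 without wild type replicate 2 and 40 without mild-dr replicate 1. DESeq2 called 328 loci and edgeR without the filter on low counts 132.

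The third comparison set the epiF3 line against wild type. Folylpolyglutamate synthase (Solyc04g016550.2), which adds glutamates to folate, was nearly absent from epiF3, at 0.0536 ± 0.0234 CPM against 29.4 ± 2.64 in wild type (SD, n = 3), and phosphatidylinositol phosphate kinase PIP5K9 (Solyc04g017620.2) stood at 0.107 ± 0.0196 against 9.05 ± 0.471. A major latex-like protein gene (Solyc04g005700.2), of a family related to the PR-10 defence proteins, was higher, at 87.2 ± 15 against 26.4 ± 5.15. An auxin F-box gene of the receptor family (Solyc06g008780.1) was lower, at 1.23 ± 0.0928 against 7.65 ± 0.652. By edgeR, 212 loci rose and 96 fell of 20391 tested, 241 of the 308 by at least 2-fold.

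The pentatricopeptide repeat gene Solyc06g009490.2 was at least 55.8-fold higher in epiF3 than the 0 counts of wild type, inositol-3-phosphate synthase (Solyc04g050810.1) at least 37.9-fold, and a KDO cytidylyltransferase (Solyc04g079020.2), of cell wall sugar synthesis, at least 36.3-fold (fitted log2 9.90, and 9.31 without epiF3 replicate 2). The NBS-LRR gene Solyc09g092290.1 rose by 6.02 ± 0.32 on the log2 scale and a germin-like gene (Solyc01g088270.2) by 6.01 ± 0.44. Falls were seen in folylpolyglutamate synthase (−8.97 ± 0.21, edgeR adjusted p = 8.97e-08), the serine/threonine kinase Solyc08g082980.2 (−6.83 ± 0.25, and −7.52 without epiF3 replicate 1) and PIP5K9 (−6.34 ± 0.22). A leucine-rich repeat receptor-like gene (Solyc11g016930.1) fell by 4.50 ± 0.18 and a CCCH zinc finger gene (Solyc04g064770.1) by 3.86 ± 0.50 (−3.09 without wild type replicate 1). PROTODERMAL FACTOR 2 (Solyc06g035940.2) varied within epiF3, at 15.9, 1.45 and 0.121 CPM in replicates 1 to 3. It fell by 5.16 ± 0.90 (edgeR adjusted p = 0.0227), or −8.00 without epiF3 replicate 1, with an adjusted p of 0.069 without wild type replicate 2 and 0.13 without epiF3 replicate 2. Those named for epiF3 differed the same way in 3 of 3 libraries, again required by the rule for the largest changes.

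The pathogenesis-related list had 13 rises and 0 falls of 67 in epiF3 by edgeR, a direction that did not pass Fisher's exact test (adjusted p = 0.0669, but 0.00428 without wild type replicate 1 and 0.0365 without wild type replicate 3). By limma's camera it was not called either (adjusted p = 0.108 at the preset and 0.955 with an estimated correlation). Most of the risers were major latex-like proteins, including Solyc04g005700.2 and Solyc08g023660.2, up by 1.72 ± 0.16 and 1.72 ± 0.17 (edgeR adjusted p = 0.000687 and 0.000909). Trichome markers had 5 rises of 9 (Fisher's exact test, adjusted p = 0.326). Limma's camera called this list at the preset correlation (adjusted p = 0.0469) but not with an estimated correlation (adjusted p = 0.955). Its risers include a humulene and caryophyllene synthase (Solyc07g051940.2) with a count ratio of 32.9 (95% interval 8.81 to 277). Another is Solyc06g059910.2, up by 1.38 ± 0.22 (edgeR adjusted p = 0.013, and 0.0803, 0.0802 and 0.0717 without wild type replicate 2, epiF3 replicate 2 or epiF3 replicate 3). Pentatricopeptide repeats had 5 rises of 37 (Fisher's exact test, adjusted p = 0.326), such as Solyc05g014490.1, up by 1.71 ± 0.09 (edgeR adjusted p = 2.68e-05). Auxin had 4 falls of 38, the F-box gene by 2.63 ± 0.16 (edgeR adjusted p = 5.03e-05) and auxin response factor 6 (Solyc07g043610.2) by 0.55 ± 0.09 (edgeR adjusted p = 0.0144, and 0.0789, 0.0918 and 0.101 without the same 3 libraries). Lipid transfer and cuticle genes had 4 rises of 47, led by lipid-transfer protein Solyc06g005780.1, up by 1.80 ± 0.20. Phenylpropanoid genes had 3 rises and 1 fall of 31, with 2 phenylalanine ammonia-lyases (Solyc09g007920.2 and Solyc09g007900.2) up by 0.47 ± 0.09 and 0.46 ± 0.09. Both lost their calls, at edgeR adjusted p of 0.193 and 0.206 without wild type replicate 2, 0.0921 and 0.107 without wild type replicate 3, and 0.173 and 0.187, 0.102 and 0.0775, and 0.157 and 0.177 without epiF3 replicate 1, 2 or 3. Adjusted over the list alone, 21 pathogenesis-related, 8 trichome, 10 pentatricopeptide repeat and 13 auxin members passed. Ethylene, oxidative stress and flowering genes had 2 rises each, of 40, 67 and 24. Heat shock and chaperone genes had 3 falls of 56 and gibberellin genes 3 rises of 19, of which 2, ent-kaurene and ent-copalyl diphosphate synthase, also count as trichome markers. Cell cycle had 0 called members by edgeR, where 1670 of all loci had an unadjusted p under 0.05, as had 12 other lists.

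The 308 calls in epiF3 became 893 without wild type replicate 1, 188 without wild type replicate 2 and 201 without epiF3 replicate 2.

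Calls were counted by chromosome, without a test of the counts. In Dwarf-dr the widest gap was on chromosome 02, with 12.3% of the calls against 10.7% of the tested loci. In mild-dr, chromosome 10 held 14 of the 74 (18.9%) against 6.58%. In epiF3, chromosome 04 held 49 of the 308 (15.9%) against 8.27%, among them folylpolyglutamate synthase, PIP5K9, the CCCH zinc finger gene, inositol-3-phosphate synthase and the KDO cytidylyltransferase.

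**Figure D3:**
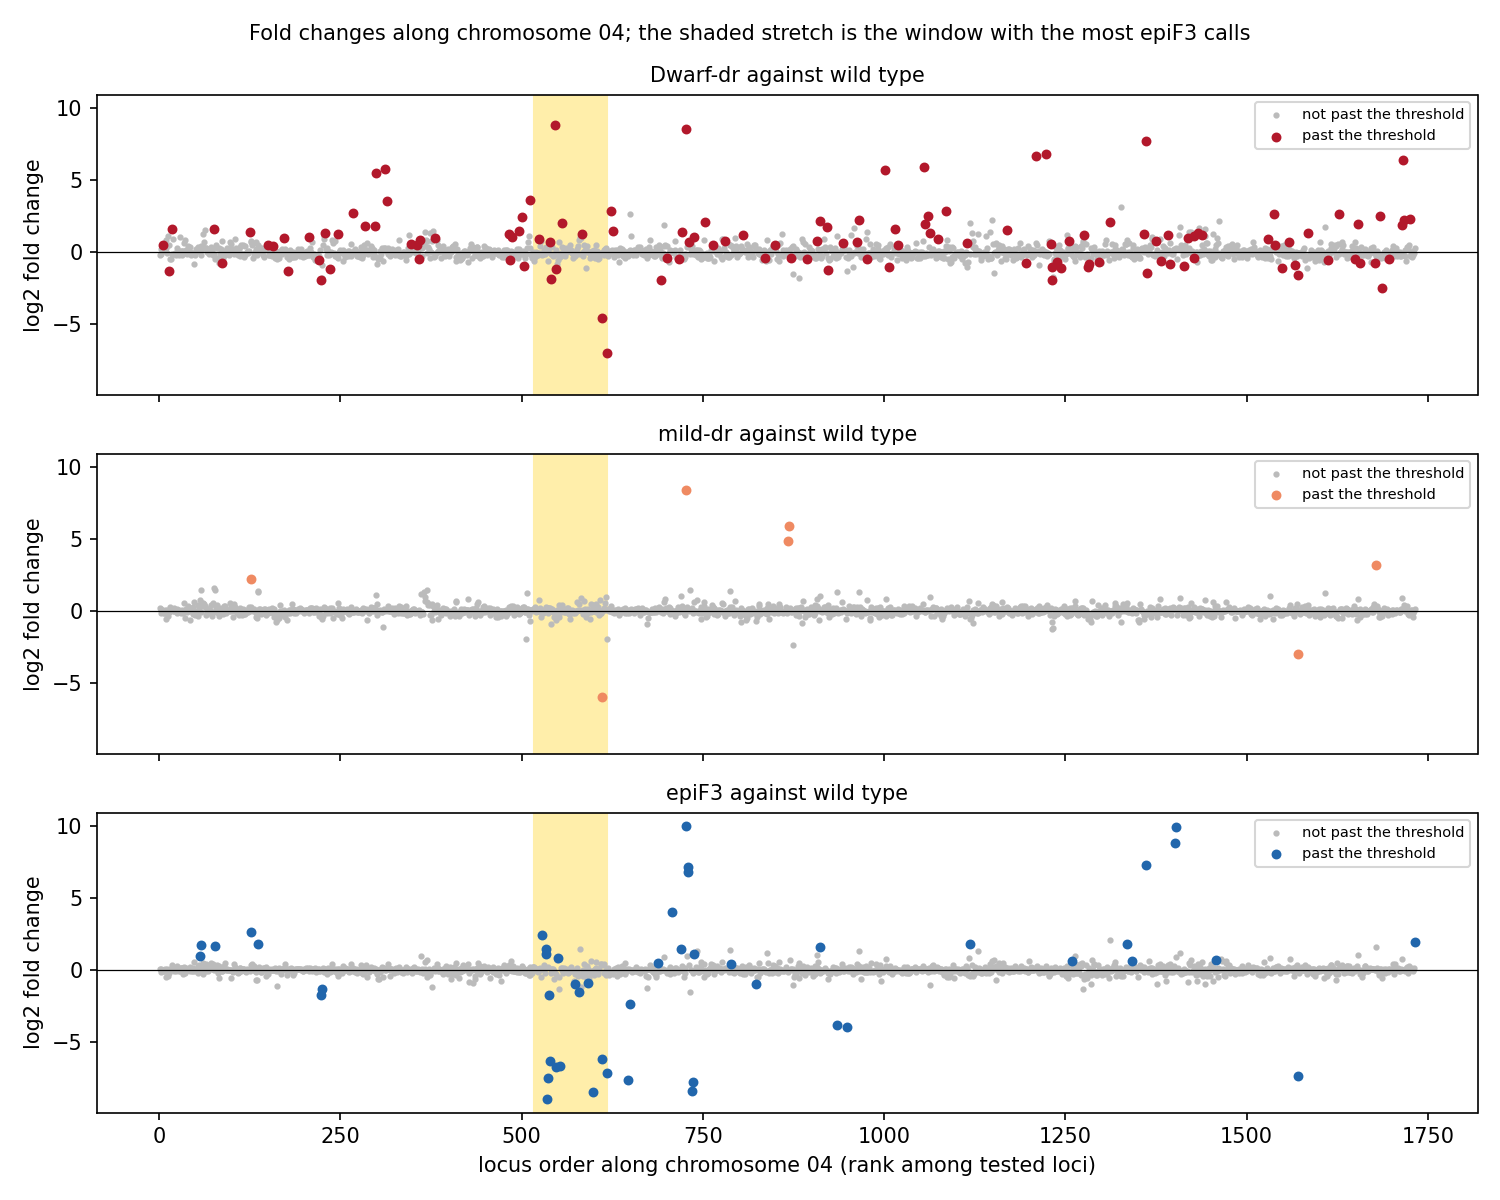
Log2 fold change against wild type of each tested locus on chromosome 04, in identifier order, for Dwarf-dr, mild-dr and epiF3; coloured points passed edgeR's test, and the shaded stretch is the window of 100 tested loci with most epiF3 calls. It holds 16 epiF3 calls, 9 in Dwarf-dr and 1 in mild-dr. Of all tested loci, 1.51% were called in epiF3, 8.345% in Dwarf-dr and 0.3647% in mild-dr.

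The lines were also compared with each other, first Dwarf-dr with mild-dr. Alternative oxidase (Solyc08g075540.2) was higher in Dwarf-dr by 5.13 ± 0.17 on the log2 scale (edgeR adjusted p = 2.66e-05), TIM14 (Solyc06g072330.2) by 5.70 ± 0.22 and GH3.8 (Solyc01g107400.2) by 7.10 ± 0.27. PROTODERMAL FACTOR 2 (Solyc06g035940.2) was lower, at 0.146 ± 0.12 against 178 ± 40.3 CPM (log2 −10.1, and −11.1 without Dwarf-dr replicate 3), and so was the HAT gene (Solyc04g057790.1), at least 28.2-fold. By edgeR, 1762 loci were higher in Dwarf-dr and 1184 lower of 20536. In the cell cycle list 44 of 52 members were lower and 3 higher (Fisher's exact test, adjusted p = 1.94e-13), a call that limma's camera gave at the preset correlation (adjusted p = 1.43e-09) and not with an estimated correlation (adjusted p = 0.317). Examples are B-like cyclin Solyc04g082430.2, lower by a log2 difference of −0.88 ± 0.07 (edgeR adjusted p = 0.000646), and kinesin Solyc03g114380.2, by −1.22 ± 0.10 (edgeR adjusted p = 0.00074). NAC factors had 11 members higher and 0 lower of 16 by edgeR (Fisher's exact test, adjusted p = 0.0329) and the cuticle list 12 higher and 23 lower of 49 (adjusted p = 0.0326), and in limma's camera these had an adjusted p = 0.00739 and 0.0184 at the preset correlation and 0.317 each with an estimated correlation. NAC gene Solyc02g077610.2 was higher by 3.80 ± 0.17 (edgeR adjusted p = 4.57e-05). The 2946 calls became 7003, 1460 and 1562 without Dwarf-dr replicate 1, 2 or 3, and 1294, 1252 and 1132 without mild-dr replicate 1, 2 or 3.

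Between Dwarf-dr and epiF3, alternative oxidase was higher in Dwarf-dr by 5.46 ± 0.13 (Solyc08g075540.2, edgeR adjusted p = 1.67e-06), and an ACC oxidase-like gene (Solyc12g006380.1) stood at 277 ± 9.5 against 3.18 ± 0.454 CPM. Folylpolyglutamate synthase (Solyc04g016550.2) was higher in Dwarf-dr by 9.08 ± 0.18 (edgeR adjusted p = 1.23e-06). Lower in Dwarf-dr were the KDO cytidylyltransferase gene (Solyc04g079020.2), at least 31.7-fold (fitted log2 −9.84, and −9.24 without epiF3 replicate 2), and CER1 (Solyc00g278110.2), of wax alkane synthesis, at 0.718 ± 0.245 against 5.59 ± 0.777. By edgeR, 1791 loci were higher in Dwarf-dr and 1178 lower of 20772. Lists with a called direction were cell cycle (2 members higher and 39 lower of 51, Fisher's exact test, adjusted p = 2.91e-12), oxidative stress (41 and 10 of 75, adjusted p = 0.0123), lipid transfer and cuticle (9 and 24 of 50, adjusted p = 0.00308) and NAC (10 and 0 of 16, adjusted p = 0.0466). Limma's camera called all 4 at the preset correlation (adjusted p = 4.45e-08, 0.0283, 0.0296 and 0.0112) and none with an estimated correlation (adjusted p = 0.62, 0.433, 0.702 and 0.433). A MADS-box gene of the flowering list (Solyc03g006830.2) was lower in Dwarf-dr, at 1.72 ± 0.204 against 7.07 ± 0.411. The 2969 calls became 7076, 1431 and 1502 without Dwarf-dr replicate 1, 2 or 3, and 1673, 1137 and 1053 without epiF3 replicate 1, 2 or 3.

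Between mild-dr and epiF3, 185 loci were higher in mild-dr and 230 lower of 20520 by edgeR. Higher in mild-dr were folylpolyglutamate synthase (Solyc04g016550.2, by 8.98 ± 0.25, edgeR adjusted p = 6.83e-09), PIP5K9 (Solyc04g017620.2, by 6.51 ± 0.20) and the CCCH zinc finger gene (Solyc04g064770.1), at 65.7 ± 2.96 against 1.78 ± 0.368 CPM. Lower were a MADS-box gene (Solyc07g052700.2), at 0.267 ± 0.38 against 6.43 ± 1.55 (log2 −4.47, and −6.92 without mild-dr replicate 1), and a lipase gene (Solyc02g090930.2), at 2.22 ± 0.573 against 12.1 ± 0.752. The plastid homologs for the Rubisco large subunit (Solyc01g007330.2) and CP47 (Solyc01g007500.2) were lower in mild-dr by log2 differences of −0.94 ± 0.08 and −1.01 ± 0.10 (edgeR adjusted p = 9.34e-05 and 0.000285, but 0.148 and 0.12 with all 12 libraries in a single fit). No list had a called direction between these lines. At the preset correlation limma's camera called cell cycle (higher, adjusted p = 0.00442) and photosynthesis (lower, adjusted p = 0.00862), but in none of the 6 comparisons did limma's camera call a list with an estimated correlation. The 415 calls became 222 without mild-dr replicate 3, 259 without epiF3 replicate 2 and 251 without epiF3 replicate 3. In all 3 comparisons of lines, the named genes differed the same way in 3 of 3 libraries, by the same rule.

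Calls were shared between the comparisons against wild type. Dwarf-dr and mild-dr shared 44 loci moving the same way, 30 up and 14 down, where independent lists would share 2.25 and 0.492 and the simulated unchanged groups 0. Simulated unchanged groups have almost no calls to share, so their value near 0 says nothing of what shared controls add to the overlap of real calls. Dwarf-dr and epiF3 shared 145, 94 up and 51 down (9.62 and 2.43 for independent lists, 0 simulated), and mild-dr and epiF3 shared 44, 34 up and 10 down (0.395 and 0.0906, with 0.05 simulated). Opposite calls numbered 1, 2 and 0. Across genes, which are not independent replicates, log2 fold changes correlated at 0.467, 0.508 and 0.608 against 0.504, 0.503 and 0.509 simulated. Their covariance was 0.106, 0.158 and 0.0969 against 0.0277, 0.0275 and 0.0277 simulated, a difference of 0.0782, 0.13 and 0.0691. Loci with large fitted changes weigh most in a covariance. An example is Solyc06g009490.2, with 0 counts in wild type and 10.1, 9.27 and 10.5 in Dwarf-dr, mild-dr and epiF3 on the log2 scale. How much of the difference rests on such loci was not computed. The share of genes with the same sign was 55.5%, 57% and 67.6% against 66.7%, 66.8% and 67% simulated, so lower in both pairs with Dwarf-dr. The 3 wild type libraries cannot be divided into separate sets of at least 2, so part of the excess may come from the shared controls.

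In all 3 lines 23 loci rose and 7 fell of 19976 tested in each. They include the NBS-LRR gene (Solyc09g092290.1), up by 6.26 ± 0.33, 5.81 ± 0.31 and 6.02 ± 0.32 in Dwarf-dr, mild-dr and epiF3, and adenosine kinase (Solyc09g007940.2), up by 4.36 ± 0.11, 4.83 ± 0.32 and 5.12 ± 0.10. The serine/threonine kinase Solyc08g082980.2 fell in each, with log2 fold changes of −6.11 ± 0.30, −1.16 ± 0.11 and −6.83 ± 0.25 (−6.95 in Dwarf-dr without its replicate 2 and −7.52 in epiF3 without its replicate 1). Among the others, chosen after their values were seen, are cell wall invertase (Solyc10g083300.1, a beta-fructofuranosidase that splits sucrose), up by 2.30, 2.19 and 1.66, and glutamate dehydrogenase (Solyc05g052100.2), up by 1.07, 0.94 and 0.97.

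Set beside the authors' deposited tables, 1554 of their 3165 loci for Dwarf-dr were also called here, 58 of 341 for mild-dr and 253 of 473 for epiF3. With DESeq2, which the submitters' notes name, 2294, 235 and 370 of the loci in the authors' deposited tables were called here. All 3049, 337 and 451 that could be tested here had the sign that the authors' table gives. Those tables come from the same libraries and hold only loci already called, so the shared sign is no independent evidence.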

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

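The tests of position along the genome, of a shared day or batch, and of other splits of the libraries were chosen only after the results they bear on had been seen.

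The 3 lines differed from each other as well as from wild type, at 2946 loci between Dwarf-dr and mild-dr, 2969 between Dwarf-dr and epiF3 and 415 between mild-dr and epiF3 (edgeR, direct tests of the differences). A few loci passed the test against wild type in opposite directions in 2 lines. A terpene synthase locus, Solyc06g059900.2, had a log2 fold change of −0.49 in Dwarf-dr and 0.68 in mild-dr, and the direct test gave −1.18 for Dwarf-dr against mild-dr (edgeR adjusted p = 0.000313, 3 of 3 libraries). PIP5K9, Solyc04g017620.2, had 0.71 in Dwarf-dr and −6.34 in epiF3, with 7.04 for Dwarf-dr against epiF3 (edgeR adjusted p = 3.47e-06, 3 of 3 libraries). A class I small heat shock protein gene, Solyc06g076520.1, had 0.88 in Dwarf-dr and −0.79 in epiF3, with 1.67 between them (edgeR adjusted p = 0.000844, 3 of 3 libraries).

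The first pattern is that 61 genes were on, at 1 CPM or more in every library, in at least 1 group, and off, at no more than 3 counts over the libraries, in another, where Dwarf-dr had 33 that were off in wild type, mild-dr 7 and epiF3 21, and Dwarf-dr lacked 10 that wild type had, mild-dr 4 and epiF3 8. Of the 61, 16 (26.2%) had another such gene within 20 detected loci. Random sets of the 19062 expressed loci had a median of 5, a 95th percentile of 10 and a highest value of 19 (permutation p = 0.002). A candidate explanation is therefore blocks of linked sequence that differ between the lines and this wild type. The random sets do not keep neighbouring copies of a gene together, so the test cannot tell such copies from linked sequence. Some neighbours share a product name, such as the Yippee-like loci Solyc03g096250.2 and Solyc03g096260.1. Loci on in some and off in other libraries of the same group gave 99 cases, 65 of them in Dwarf-dr and 6 in wild type, with some loci counted in more than 1 group, and 11 of their 12 neighbouring pairs were on in the same libraries (shuffled median 6, permutation p = 0.0013). Only 2 of those pairs lie outside Dwarf-dr, a restriction set after seeing them, and both come from Solyc03g098720.2, Solyc03g098760.1 and Solyc03g098790.1, on only in replicate 1 of mild-dr and also only in replicate 1 of Dwarf-dr. All 65 cases in Dwarf-dr set replicate 1 apart from replicates 2 and 3. A deviation of the replicates numbered 1 could alone give such matches, so blocks still segregating inside a line stay open, as does a change in gene activity without a change in sequence, which was not tested. Solyc09g005460.1 and nearby Solyc09g005430.1, chosen after their values were seen, were both highest in mild-dr replicate 3 and in epiF3 replicate 2. Solyc09g005430.1 had 0, 0 and 37 counts in mild-dr and 0, 56 and 0 in epiF3. The phosphatase 7 homolog, also among the 99 cases, had 81, 0 and 160 counts in epiF3. Whether these loci lie in a segregating block was not tested.

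The second pattern is that calls gathered along chromosomes, in epiF3 on chromosome 04, where the fullest window of 100 tested loci, from Solyc04g016290.2 to Solyc04g040010.2, held 16 calls, where 10000 random placements had a median of 7 and a highest value of 12 (permutation p = 1e-04, the smallest they can give), and 12 of the 16 fell against 84 of 292 elsewhere (one-sided Fisher's exact test, p = 0.000275). Dwarf-dr calls gathered too, with 30 on chromosome 06 from Solyc06g008010.2 to Solyc06g009510.1 (random median 19, highest 27, permutation p = 1e-04, again the smallest possible), and mild-dr had 6 on chromosome 09 (random median 3, highest 7, permutation p = 0.003). The chromosome 06 stretch holds genes named above, the pentatricopeptide repeat gene Solyc06g009490.2, the glutaredoxin gene Solyc06g008760.1 and the auxin F-box gene Solyc06g008780.1. Within it, Solyc06g008710.1, Solyc06g009420.2 and Solyc06g009490.2 rose in all 3 lines. Whether a segment there is shared by the lines was not tested. A segment of another sequence or origin in epiF3 is a candidate explanation. A segment shared by all 3 lines stays open, since the epiF3 window held 5.19% of the epiF3 calls, 0.528% of the Dwarf-dr calls (9) and 1.35% of the mild-dr calls (1). The 9 Dwarf-dr calls were among 101 tested loci, and 8.345% of all tested loci were called, so Dwarf-dr calls did not gather there. Within the window, folylpolyglutamate synthase stood at 31.6 ± 1.47 CPM in Dwarf-dr and 29.6 ± 4.27 in mild-dr, near the 29.4 ± 2.64 of wild type. Solyc04g039720.1, also within it, fell in all 3 lines. A block of altered gene activity on the same stretch, without a sequence change, was not tested.

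The third pattern is that replicate 1 of Dwarf-dr and of wild type stood apart. With all libraries thinned to the smallest total, the chi-square per degree of freedom of the pairs holding Dwarf-dr replicate 1 was 37.2 and 38.3 against 2.53 for replicates 2 and 3, a ratio of at least 14.7, and in wild type 14.2 and 22.6 against 6.24, which argues against depth. Another share of dividing tissue stays open, since the cell cycle list of replicate 1 lay at −0.134 in Dwarf-dr and 0.393 in wild type relative to replicates 2 and 3, in opposite directions. A day or batch shared by the libraries numbered 1 stays open too, as their deviations correlated at 0.315 between Dwarf-dr and wild type but at 0.000291 between Dwarf-dr and epiF3. No biological explanation was tested.

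Each comparison allows 10 splits of its 6 libraries, so no share under 0.1 can be had, and chance can be neither named nor weighed from them. The real split gave 1704 calls and the highest other 0 for Dwarf-dr against wild type, 74 and 2 for mild-dr, 308 and 1 for epiF3, 2946 and 0 for Dwarf-dr against mild-dr, 2969 and 0 for Dwarf-dr against epiF3, and 415 and 0 for mild-dr against epiF3. In each, 1 split, the real one, gave as many. Dwarf-dr and wild type samples looked paired by number. There the 3 other splits that part all 3 pairs and the 6 that part 1 pair gave 0 calls in edgeR, against 1704 in the real split. The real split had 4940 loci at an unadjusted p under 0.05, a count not made for the other splits. A split that mixes the groups carries the difference between them in its spread, so its few calls do not measure chance.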

How the results depend on the processing

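The fit without both libraries numbered 1 and every test of list directions were chosen after seeing the data, the other alternatives before. Of the genes the naming rule selected, not all of which are named, 24 of 27 for Dwarf-dr against wild type kept their direction and their call under every alternative that tested them, as did 9 of 20 for mild-dr, 17 of 23 for epiF3, 26 of 28 for Dwarf-dr against mild-dr, 29 of 30 for Dwarf-dr against epiF3 and 11 of 24 for mild-dr against epiF3, and none reversed. The stricter filter tested only 22, 12, 16, 25, 25 and 15 of them. Of the alternatives for counts and for the MSH1 test, 102 left a count within 1.5 times its reported value or the MSH1 direction and outcome unchanged, and 76 moved a count further. The cause of the moves was not tested. Pseudocounts and the settings for tables of p-values alone do not apply to counts and were not run.

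With at least 5 CPM in 3 libraries, calls numbered 1053 for Dwarf-dr, 26 for mild-dr and 145 for epiF3 against wild type and 236 for mild-dr against epiF3. Against a minimum fold of 1.5 they numbered 507, 33 and 190, and 554 for Dwarf-dr against mild-dr, 595 for Dwarf-dr against epiF3 and 94 for mild-dr against epiF3. With all 12 libraries in a single fit there were 3983 for Dwarf-dr against wild type and 148 for mild-dr against epiF3. For mild-dr against wild type DESeq2 called 328 and edgeR without a filter 132. Without both libraries numbered 1, Dwarf-dr against wild type had 5416.

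With each library left out in turn, calls ranged from 665 to 3125 for Dwarf-dr against wild type (highest without Dwarf-dr replicate 1, lowest without wild type replicate 2), 28 to 1327 for mild-dr and 188 to 893 for epiF3 (highest without wild type replicate 1, lowest without wild type replicate 2), 1132 to 7003 for Dwarf-dr against mild-dr, 1053 to 7076 for Dwarf-dr against epiF3 (both highest without Dwarf-dr replicate 1), and 222 to 437 for mild-dr against epiF3.

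With the replicate block, calls numbered 2246 for Dwarf-dr against wild type, 85 for mild-dr, 243 for epiF3, 2075 for Dwarf-dr against mild-dr, 1575 for Dwarf-dr against epiF3 and 463 for mild-dr against epiF3. Outside Dwarf-dr and wild type the samples did not look paired by number, with same-number correlations as low as −0.188 and between 2 and 4 of 6 libraries correlating best with their own number. For Dwarf-dr and wild type the block changed the call of the NAC and flowering lists, of no other list and of none of the 27 genes the naming rule selected. Other named genes were not checked with it. Against wild type the block lost the call of 4 of 20 selected genes for mild-dr and 4 of 23 for epiF3. In mild-dr these included the 3-ketoacyl-CoA synthase, the sesquiterpene synthase and Solyc04g007680.2 (edgeR adjusted p = 0.0594, 0.0611 and 0.0615). In epiF3 they were Solyc06g059910.2, auxin response factor 6 and both phenylalanine ammonia-lyases (edgeR adjusted p = 0.0611, 0.0703, 0.0958 and 0.0893). Of 24 for mild-dr against epiF3, 1 was lost.

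The 372 called list members of Dwarf-dr became 235 with the stricter filter, 673 without both libraries numbered 1 and 152 to 551 with a library left out. The 12 of mild-dr became 1 and 4 to 120, and the 54 of epiF3 29 and 24 to 111. Lists with a called direction numbered 3 in Dwarf-dr, but 7 with camera at the preset correlation, 0 with an estimated correlation, 22 with fry, which asks only whether members move on balance, 5 with the replicate block, 6 without both libraries numbered 1 and 2 to 9 with a library left out. In mild-dr they numbered 0, but 5 with camera and 6 with fry, and in epiF3 0, but 1 with camera, 2 with fry, 1 with the other scaling and 0 to 1 with a library left out.

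The MSH1 locus passed in Dwarf-dr with all 12 libraries in a single fit (1.72, edgeR adjusted p = 0.0202). In epiF3 its log2 fold change reversed without epiF3 replicate 2 (−0.234, range −0.234 to 0.323 with a library left out), without passing. At an adjusted p of 0.01, shared calls numbered 25 for Dwarf-dr and mild-dr, 81 for Dwarf-dr and epiF3 and 20 for mild-dr and epiF3.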

Other observations

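The genes named here, and the test of the mild-dr window, were chosen after the results had been seen.

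Single genes of gibberellin metabolism differed in Dwarf-dr, in a list without a called direction (8 rises and 2 falls of 19, Fisher's exact test, adjusted p = 0.843). Of 4 tested gibberellin 2-oxidases, which inactivate the hormone, 3 rose against wild type, Solyc07g061720.2 by 3.39 ± 0.24 on the log2 scale (edgeR adjusted p = 0.000269), Solyc02g070430.2 by 1.99 ± 0.35 (edgeR adjusted p = 0.0152) and Solyc07g056670.2 by 1.62 ± 0.38 (edgeR adjusted p = 0.0419). The other, Solyc01g058030.1, was lower without passing (−2.04 ± 0.51, edgeR adjusted p = 0.0505). Both gibberellin 20-oxidases of the list, which make its precursors, fell, Solyc03g006880.2 by 1.18 ± 0.16 (edgeR adjusted p = 0.00434) and Solyc06g035530.2 by 1.98 ± 0.30 (edgeR adjusted p = 0.00836). In mild-dr and epiF3 these 6 genes did not pass where they were tested, with log2 fold changes for Solyc07g061720.2 of 0.02 and 0.40 and for Solyc03g006880.2 of 0.06 and −0.07. Cytokinin genes also went both ways in Dwarf-dr, with a gene for an enzyme that activates cytokinin ribosides (Solyc01g005680.2) up by 2.12 ± 0.30 and a cytokinin oxidase gene (Solyc04g080820.2), which degrades the hormone, down by a log2 difference of −1.11 ± 0.18.

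The 4 neighbouring loci Solyc09g092290.1, Solyc09g092300.2, Solyc09g092310.1 and Solyc09g092320.2 on chromosome 09, of which the first 3 are described as resistance proteins of the NBS class, rose in all 3 lines. Their log2 fold changes were 6.26, 3.84, 3.94 and 2.29 in Dwarf-dr, 5.81, 3.27, 3.51 and 1.85 in mild-dr and 6.02, 3.30, 3.42 and 1.76 in epiF3. They are 4 of the 6 calls that make up the fullest window of mild-dr calls (6 of 74 in 100 tested loci, permutation p = 0.003). That p-value rests on these same calls and is no further evidence about them. A Mutator-like transposase locus (Solyc10g054690.1) had reads in wild type and 0 in each line. In epiF3, the MADS-box gene Solyc07g052700.2 rose by 3.70 ± 0.33 (edgeR adjusted p = 0.00049) and SELF PRUNING 5G (Solyc05g053850.2), a repressor of flowering in tomato, by 1.90 ± 0.26 (edgeR adjusted p = 0.00553). A histone H3 gene (Solyc01g073970.2) fell by 1.96 ± 0.35 in Dwarf-dr, and ARGONAUTE 1 (Solyc02g069260.2), of small RNA silencing, rose by 0.81 ± 0.13.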
